A study of Mus musculus with 6 samples.

How the data were processed

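The series compares 2 compartments of the wild-type FVB/N mouse bladder at embryonic day 13, separated after 20 minutes in 20 µM EDTA, with 3 arrays each. Total RNA was purified on columns, amplified in 2 rounds and labelled with biotin, per the labels' protocols. The deposited values are array intensity on a linear scale, 1 value for each of 45101 probe sets, and the submitters' processing notes name GCOS, Affymetrix's operating software; the algorithm and its settings are not given in the sources used here. The 2% trimmed mean of every array was 1500, so the arrays were taken as already scaled and were not scaled again. Signals ran from 0.09 to 156866. No detection calls were used here, so a low signal is not said to be absent. Median signals were 240, 183 and 161 on mesenchyme 1, 2 and 4, and 132, 172 and 192 on epithelium 5, 7 and 8. Such scaling sets a common mean on each array and would hide a difference in total RNA per cell, and the background of dim probe sets compresses their differences.

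Probe sets were named through the platform's annotation. Of the 45101 probe sets 64 were controls and were left out, 34945 had a single gene symbol, 932 had several and 9160 had none; those with several or none named no gene. Symbols were checked through Entrez identifiers against a RefSeq gene table, which matched 34741 of the 34945 and changed 0 symbols. For each of 18193 genes the probe set with the highest mean over all arrays was used. There were 9010 genes with more than 1 probe set, and no gene named by the rule below had a probe set past the test in the opposite direction. No genome build is given, so no coordinates are printed.

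Signals were transformed as log2(signal + 45), where 45 is the 25th percentile of all values. A linear model with the compartment as its factor was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend). P-values were adjusted by the method of Benjamini and Hochberg over 18193 genes, and genes with adjusted p under 0.05 passed. Log2 differences are given with the moderated standard error and mean signals with the SD of 3 arrays. The replicate numbers of the compartments do not overlap, so no pairing was possible. The sources used here give no batch or date.

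Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and adjustment over 22 lists. The calls of 13 lists passed, and 8 of these also passed with a correlation estimated from the data: epithelial junctions and keratins, uroplakins and urothelial differentiation, epithelial and mesenchymal transcription factors, fibroblast and matrix genes, hedgehog reception and response, endothelial markers and macrophage markers. With that estimate the camera adjusted p of the 8 lists lay between 0.00327 and 0.0330. The far smaller values given for these lists below rest on the preset correlation. A further list of sex-linked genes was read per array and not tested. Of 520 different genes in the lists 31 had no probe set with a single symbol. Some genes stand in more than 1 list.

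The test, its arrays, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where a later choice is stated. The rule named the 8 genes with the largest log2 difference in each direction among those past the test without overlap between compartments, leaving out clone-like symbols and red cell genes. It also named up to 3 members of each list with the largest difference past the test, or those with the highest signal where fewer than 2 passed. It added Shh, Ptch1, Gli1, Bmp4, Fgf10, Fgfr2, Wnt5a, Wnt7b, 5 uroplakin genes, Acta2, Myh11 and Myocd whether or not they passed, and the sex-linked genes. This gave 82 genes apart from the last group.

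The fit was tested on simulated data of 18193 genes with the means and spread of this comparison, in which 200 genes differed, 50 at each size. It recovered 8% of genes with a 2-fold difference, 76% at 4-fold, 100% at 16-fold and 100% at 64-fold, with 13 false among 155 calls. In the list test on simulated data, the shifted list had an adjusted p of 1.13e-23 and 0 of 21 other lists passed. Genes were simulated independently of each other, so this cannot show how the list test fares when members of a list are correlated. The sizes of difference and the recovery required were revised after a first run of the simulation fell short of its requirement. These shares hold for that simulation, which had fewer calls than the real comparison and so a stricter threshold on the unadjusted p.

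Alternatives were pseudocounts of 1 and 179, quantile normalization, arrays centred on their medians, a filter on dim genes, no intensity trend, array weights, the mean of a gene's probe sets, every probe set by itself, a further 2-fold threshold, an estimated correlation in camera, and leaving out each array in turn. After the data were seen, a fit with the beta-actin 3' to 5' ratio as a covariate and a fit of 4 arrays without mesenchyme 1 and epithelium 5 were added.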

Results

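Gene expression was measured in the bladder of FVB/N mouse embryos at embryonic day 13 (Theiler stage 21), when the organ consists of an epithelium, the future urothelium, inside a sleeve of mesenchyme. The bladder was freed by microdissection above the ureters and soaked in EDTA, a chelator of divalent cations that loosens epithelium from the tissue around it. The compartments were then parted with a needle, and their RNA was hybridised to Affymetrix MOE430 arrays after 2 rounds of amplification. There were 3 mesenchyme arrays (replicates 1, 2 and 4 by their labels) and 3 epithelium arrays (replicates 5, 7 and 8). The labels do not say that the arrays came from separate embryos, so the p-values measure the spread between these samples, which can be technical. The number of arrays limits the precision, and 18193 genes were tested.

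The arrays of each compartment resembled each other more than those of the other compartment. Over all genes, Pearson's r was 0.940 to 0.983 between mesenchyme arrays, 0.959 to 0.974 between epithelium arrays and 0.864 to 0.899 across compartments; genes are not independent replicates. Mesenchyme 1 and epithelium 5 had the highest ratio of 3' to 5' beta-actin signal, a measure of how far the amplified RNA reaches from the 3' end, at 8.40 and 8.60, against 2.29 to 4.89 on the other 4 arrays. Both also had the lowest 18S rRNA signal, 5290 and 3513, against 21829 to 64661 on the other arrays. The median signal of the hybridisation control probe sets was highest on both, 16043 and 16510, against 6895 to 10303 on the other arrays. The 3' to 5' ratio of Gapdh did not set both apart: it was highest on epithelium 5, at 26.3, but 11.5 on mesenchyme 1, below mesenchyme 2 (14.2), mesenchyme 4 (15.7) and epithelium 7 (15.0) and above epithelium 8 (9.77). Mesenchyme 1 and epithelium 5 belong to different compartments, and counts without them are given for some of the gene groups.

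**Figure D1:**
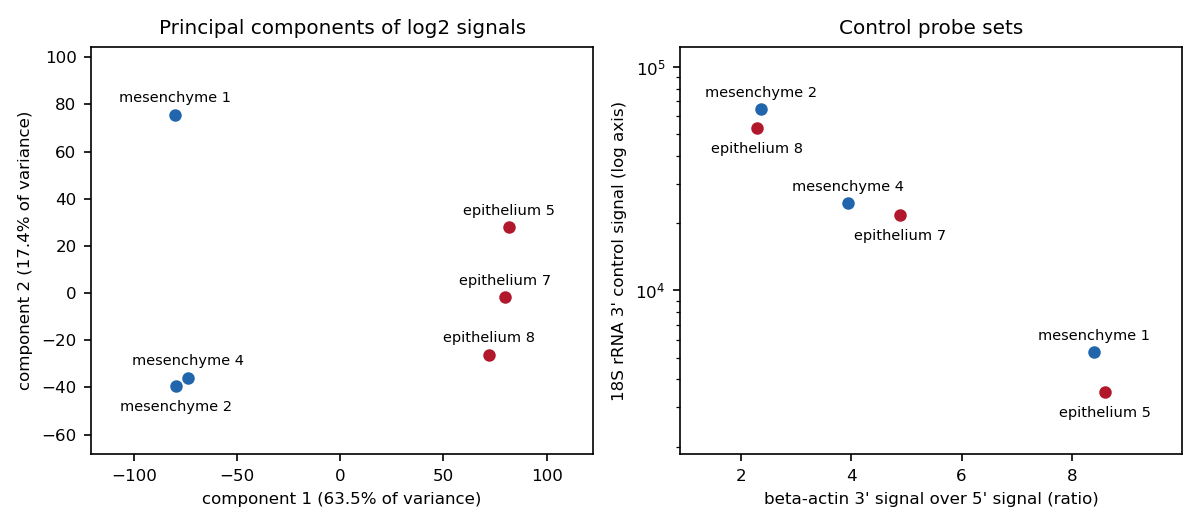
Left, the first and second principal components of the log2 signals of 18193 genes, in arbitrary units, with 1 point per array (blue, mesenchyme; red, epithelium). Right, the 18S rRNA 3' control signal on a log axis against the ratio of 3' to 5' beta-actin signal; the first component, with 63.5% of the variance, parts the compartments, and mesenchyme 1 and epithelium 5 lie at ratios of 8.40 and 8.60.

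The question the design poses is which genes distinguish the epithelium from the mesenchyme of the early bladder. Shh, which encodes the secreted hedgehog ligand, had a signal of 85468 ± 18394 (SD, n = 3) in epithelium and 265.3 ± 53.9 in mesenchyme, a log2 difference of 8.10 ± 0.28 (SE). Trp63, a transcription factor of basal cells in stratified epithelia, gave 31875 ± 9984 against 58.3 ± 15.2, a log2 difference of 8.24 ± 0.33. In the other direction, the mesenchymal cadherin gene Cdh11 had 25408 ± 12351 in mesenchyme and 284.4 ± 73.2 in epithelium, a log2 difference of −6.14 ± 0.42. The limma adjusted p was 2.77e-07 for Shh, 4.98e-07 for Trp63 and 5.10e-06 for Cdh11. Log2 differences are epithelium minus mesenchyme on the log2(signal + 45) scale, which understates the change of dim genes.

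In all, 1055 genes were higher in epithelium and 1621 were higher in mesenchyme, together 14.7% of those tested. Differences of at least 16-fold were found for 135 and 188 genes. Of the 2676 genes past the test, 99.7% had no overlap between the arrays of the compartments. Over all genes 30.1% had none, where chance gives 10%. The other genes with the largest differences towards epithelium were Clca1 (8.09), the pioneer transcription factor gene Foxa1 (7.92), the keratin gene Krt15 (7.49), the E-cadherin gene Cdh1 (7.42), the splicing regulator gene Esrp1 (7.32) and Tfap2c (7.26). Towards mesenchyme they were Sparcl1 (−5.83), Prss35 (−5.82), Vwf (−5.78), Myl9 (−5.76), the collectin gene Colec11 (−5.76), the adhesion molecule gene Vcam1 (−5.73) and the laminin chain gene Lama4 (−5.71). The adjusted p of these genes lay between 1.34e-06 and 9.83e-05. Without epithelium 7 the count of genes higher in epithelium was 660. Without mesenchyme 1 and epithelium 5 the counts were 1225 and 1731, and 2376 of the 2676 genes were past the test again in the same direction.

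**Figure D2:**
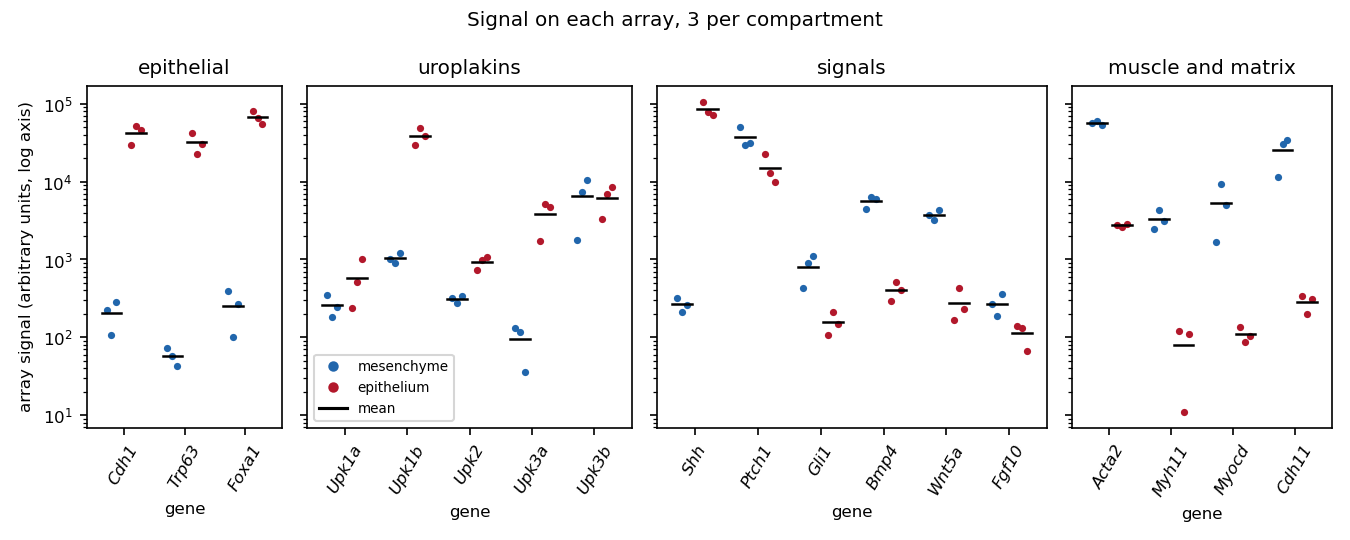
Array signal on a log axis, in arbitrary units, of 18 named genes on 3 mesenchyme (blue) and 3 epithelium (red) arrays, with each point an array and each bar the mean. Shh averages 265.3 in mesenchyme and 85468 in epithelium, Acta2 56070 and 2739, and the points of Upk3b overlap.

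In the list of epithelial junctions and keratins, 29 of 29 measured members were higher in epithelium, with a median log2 difference of 4.49. The camera adjusted p was 3.95e-42, and 0.00639 with an estimated correlation. The keratin genes of this list are Krt7, Krt8, Krt18 and Krt19, and the keratin family is counted further below. Cdh1 differed by 7.42 ± 0.36, Esrp1 by 7.32 ± 0.38 and Perp, a gene of desmosomes, by 7.13 ± 0.30. Adjusted over the list alone the count was also 29, as it was without mesenchyme 1 and epithelium 5. The median member kept 4.25% of its epithelial signal in the mesenchyme arrays, and in mesenchyme 1 the list's log2 signals lay on average 0.18 above the mean of the mesenchyme arrays. Of 21 measured epithelial transcription factors, 17 were higher in epithelium and 1 in mesenchyme (median 3.43, adjusted p = 4.27e-19). Adjusted over the list alone the counts were 18 and 2. Without mesenchyme 1 and epithelium 5 they were 19 and 2, and with array weights the count in mesenchyme was 2. Foxa1 differed by 7.92 ± 0.39 and Tfap2c by 7.26 ± 0.49. The member higher in mesenchyme was Bnc1 (−2.74), which was chosen after its value was seen.

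Of 19 measured genes of uroplakins and urothelial differentiation, 12 were higher in epithelium and 1 in mesenchyme, with a median of 3.12 (adjusted p = 3.06e-14). Adjusted over the list alone the counts were 13 and 1, as they were without mesenchyme 1 and epithelium 5. The members that differed most were not uroplakins but Trp63 (8.24), Shh (8.10) and Krt15 (7.49). Trp63 also stands in the list of epithelial transcription factors. The uroplakins, membrane proteins that form the plaques of the urothelial surface, were not alike. Upk1b rose from 1041 ± 165 in mesenchyme to 38698 ± 9241 in epithelium (log2 difference 5.14 ± 0.27), and Upk3a from 94.3 ± 51.2 to 3883 ± 1864 (4.75 ± 0.51). Upk2 differed by 1.45 ± 0.37 (adjusted p = 0.0226). Upk1a, with signals of 259.8 ± 86.9 and 583.6 ± 391.0, differed by 0.88 ± 0.52 and was not past the test (adjusted p = 0.351), but was past it with array weights (1.11). Upk3b had 6460 ± 4350 in mesenchyme and 6227 ± 2619 in epithelium, with a log2 difference of 0.18 ± 0.58 (adjusted p = 0.902) whose sign is opposite to that of the difference in mean signals. Its signal was lowest on mesenchyme 1 (1759) and epithelium 5 (3321) within their compartments, and its other probe set showed no difference past the test (log2 difference 0.11). The gene higher in mesenchyme was the keratin gene Krt14 (−1.97), chosen after its value was seen. The call of Upk2 was lost without mesenchyme 2 (1.38), mesenchyme 4 (1.505), epithelium 7 (1.40) or epithelium 8 (1.35), and the count in mesenchyme was 0 without epithelium 7 or with only genes above the median signal.

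Mesenchyme had higher signals of fibroblast and fibrillar matrix genes, for 29 of 31 measured members (median −4.36, adjusted p = 9.67e-34). Adjusted over the list alone 30 were higher. Cdh11 led, followed by Postn, the gene of periostin (−5.70 ± 0.34), and the microfibril gene Mfap4 (−5.60 ± 0.41). The median member kept 4.75% of its mesenchymal signal in the epithelium arrays. Of 33 measured mesenchymal transcription factors 21 were higher in mesenchyme and 1 in epithelium (median −2.26, adjusted p = 3.06e-14), and adjusted over the list alone 23 and 1. Among them were Snai2 (−5.63 ± 0.27), Tbx18 (−5.06 ± 0.43) and Zeb1 (−4.85 ± 0.38). The member higher in epithelium was Isl1 (1.67), chosen after its value was seen; without mesenchyme 2, epithelium 5, epithelium 7 or epithelium 8 that count was 0, as it was in the mean of probe sets, and without mesenchyme 1 or with array weights it was 2. Without both mesenchyme 1 and epithelium 5, the counts in mesenchyme were 29 fibroblast genes and 24 transcription factors, and 2 transcription factors were higher in epithelium.

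Smooth muscle genes were higher in mesenchyme, for 15 of 20 measured members, and for 17 adjusted over the list alone, with 1 higher in epithelium (median −2.90). The list's adjusted p was 5.89e-13, but adjusted p = 0.0802 with an estimated correlation. Acta2, the smooth muscle actin gene, had 56070 ± 3369 in mesenchyme and 2739 ± 128 in epithelium, a log2 difference of −4.33 ± 0.23. Myh11, the smooth muscle myosin heavy chain gene, differed by −4.84 ± 0.49, and Myocd, the gene of the coactivator myocardin, by −4.81 ± 0.56. The differences of Myl9, Actg2 and Tagln were −5.76 ± 0.45, −5.39 ± 0.39 and −5.31 ± 0.45. In mesenchyme 1 the list's log2 signals lay on average at −0.51 from the mean of the mesenchyme arrays, and without mesenchyme 1 and epithelium 5 the count was 16.

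Shh was higher in epithelium, while 11 of 15 measured reception and response genes were higher in mesenchyme (median −2.03, adjusted p = 2.59e-09), and 12 adjusted over the list alone, or 10 without mesenchyme 1 and epithelium 5. Sfrp1 (−4.34 ± 0.30), the transcription factor gene Gli2 (−4.25 ± 0.45) and the co-receptor gene Gas1 (−4.01 ± 0.38) differed most. Sfrp1 also stands in the list of Wnt ligands, receptors and modulators. Gli1, a transcriptional target of the pathway, had 811.4 ± 343.0 in mesenchyme and 155.4 ± 51.5 in epithelium (−2.03 ± 0.46, adjusted p = 0.0119). Ptch1, the receptor gene and also a target, had 36939 ± 11505 and 15123 ± 6691 (−1.33 ± 0.35, adjusted p = 0.0252). Relative to the median gene, whose log2 difference was −0.11, the value for Ptch1 was −1.22. The call of Gli1 was lost without mesenchyme 2 (−1.92) or mesenchyme 4 (−1.78). That of Ptch1 was lost without mesenchyme 1 (−1.09), epithelium 7 (−1.26) or epithelium 8 (−1.07), with arrays centred on their medians (−1.15), without the intensity trend and in the mean of its probe sets (−0.71).

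Of 31 measured BMP and TGF-beta pathway genes, 11 were higher in mesenchyme and 2 in epithelium (median −0.68), and 13 and 2 adjusted over the list alone. The list had adjusted p = 0.00682, and adjusted p = 0.115 with an estimated correlation. The growth factor genes Tgfb3 and Gdf10 differed by −4.23 ± 0.31 and −4.06 ± 0.50, and the TGF-beta-induced matrix gene Tgfbi by −4.04 ± 0.55. Bmp4 had 5589 ± 981 in mesenchyme and 405.3 ± 106.9 in epithelium (−3.66 ± 0.32). The members higher in epithelium were the ligand gene Bmp2 (1.62) and the receptor gene Bmpr1b (1.59), chosen after their values were seen. That count was 0 without epithelium 5 or epithelium 7, and 1 without mesenchyme 1, mesenchyme 2 or mesenchyme 4, with only genes above the median signal and in the mean of probe sets. Without both mesenchyme 1 and epithelium 5, 12 were higher in mesenchyme and 0 in epithelium.

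Wnt ligands, receptors and modulators differed in both directions: 16 of 46 were higher in mesenchyme and 7 in epithelium (median −0.53), and 18 and 8 adjusted over the list alone. The list's adjusted p was 0.0313, and adjusted p = 0.311 with an estimated correlation; without mesenchyme 1 and epithelium 5 the list was not past the test. The ligand gene Wnt2 differed by −5.28 ± 0.30, the R-spondin gene Rspo2 by −4.82 ± 0.55 and Wnt5a by −3.64 ± 0.38. Wnt7b had 523.1 ± 117.7 in mesenchyme and 1352 ± 527 in epithelium, and its difference of 1.24 ± 0.41 was not past the test (adjusted p = 0.0694). It was past the test without epithelium 5 (1.58), after quantile normalization (1.43) or median centring (1.43), with only genes above the median signal (1.24), with array weights (1.48), with the actin ratio as a covariate (1.26) and without both mesenchyme 1 and epithelium 5 (1.72). The number of members higher in epithelium was 4 without mesenchyme 2, mesenchyme 4 or epithelium 7.

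Of 25 measured FGF ligands, receptors and targets, 4 were higher in mesenchyme and 3 in epithelium, all genes tested and adjusted over the list alone. The list was not past the test (median −0.15, adjusted p = 0.828), and its mean changed sign with arrays centred on their medians. Fgf9 (−2.93 ± 0.51) and the FGF target Etv5 (−2.69 ± 0.35) were higher in mesenchyme and the receptor gene Fgfr3 (2.84 ± 0.27) was higher in epithelium. Fgf10 differed by −0.9996 ± 0.42 (adjusted p = 0.168). Fgfr2 differed by 1.24 ± 0.56 (adjusted p = 0.199), and was past the test without mesenchyme 1 (1.97), with array weights (1.75) and without both mesenchyme 1 and epithelium 5 (1.65). Without mesenchyme 2 the count in mesenchyme was 2.

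Retinoic acid pathway genes were higher in mesenchyme for 4 of 19 measured members and in epithelium for 1 (median −0.29, adjusted p = 0.311), and for 6 and 3 adjusted over the list alone. Rdh10 and Aldh1a2, which encode the enzymes that make retinaldehyde and retinoic acid, differed by −3.40 ± 0.28 and −3.34 ± 0.30. Crabp2, a retinoic acid binding protein gene, differed by −1.90 ± 0.55. The call of Crabp2 was lost without mesenchyme 1 (−2.07), mesenchyme 2 (−1.77), mesenchyme 4 (−1.86) or epithelium 7 (−1.24), after quantile normalization (−1.72) and after median centring (−1.71). The count in mesenchyme was 2 without mesenchyme 2, mesenchyme 4 or epithelium 7 and with median centring, and 7 with array weights. The member higher in epithelium was Rxra (1.28), chosen after its value was seen. The count in epithelium was 0 without mesenchyme 1, mesenchyme 4 or epithelium 8, and 3 with array weights. It was 2 without epithelium 5, after quantile normalization or median centring, without the intensity trend or with the actin ratio as a covariate. Without both mesenchyme 1 and epithelium 5 it was also 2, and 5 members were higher in mesenchyme.

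Hox genes, the positional transcription factors, were higher in epithelium for 7 of 33 measured members and in mesenchyme for 3 (median 0.25), and for 9 and 6 adjusted over the list alone. The list's adjusted p was 0.0304, and adjusted p = 0.314 with an estimated correlation. Hoxb13 had 6695 ± 2908 in epithelium and 19.01 ± 14.7 in mesenchyme (6.65 ± 0.44), and Hoxd1 4283 ± 1505 and 121.0 ± 89.8 (4.76 ± 0.47). Hoxb5 differed by 2.15 ± 0.43. The members higher in mesenchyme, named after their values were seen, were Hoxc10 (−2.06), Hoxc4 (−1.94) and Hoxc8 (−1.93). The list was not past the test without mesenchyme 2, and only 1 member was higher in mesenchyme without mesenchyme 2, mesenchyme 4 or epithelium 8. That count was 5 without the intensity trend, with array weights or in the mean of probe sets, and 0 with only genes above the median signal. With array weights 12 were higher in epithelium.

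Of 29 measured genes of the basement membrane and adhesion to it, 8 were higher in mesenchyme and 7 in epithelium (median −0.0041, adjusted p = 0.828), and 11 and 9 adjusted over the list alone. Lama4 (−5.71 ± 0.62), the nidogen gene Nid1 (−5.42 ± 0.36) and Frem1 (−5.25 ± 0.46) were higher in mesenchyme. Without epithelium 7 or epithelium 8 the count in epithelium was 4. Of 27 measured cell cycle genes 0 passed limma's test in either direction, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The list median was −0.15 (adjusted p = 0.768), and the log2 differences ran from −0.91 to 0.58. Top2a, a topoisomerase gene of dividing cells, had 47155 ± 4886 in mesenchyme and 47840 ± 8919 in epithelium (0.0087 ± 0.26), and Rrm2 48571 ± 10595 and 51858 ± 15470 (0.072 ± 0.30). The list's mean changed sign with arrays centred on their medians, and without epithelium 8 the count in mesenchyme was 1. It was 2 with the actin ratio as a covariate and 3 with array weights, which also put 1 gene higher in epithelium.

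**Figure D3:**
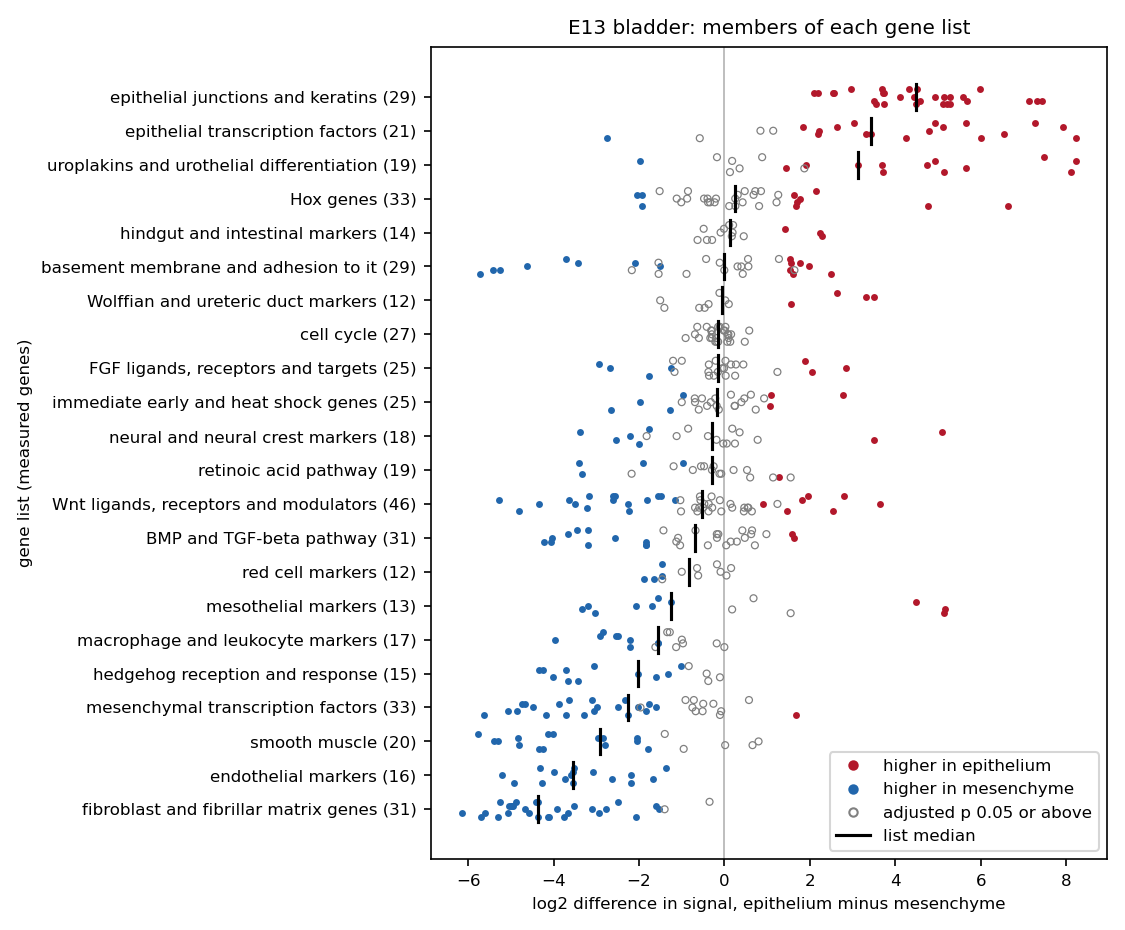
Log2 difference in signal, epithelium minus mesenchyme, of the measured members of 22 gene lists, with each point a gene and the measured number in parentheses. Filled points passed the limma test over 18193 genes (red, higher in epithelium; blue, higher in mesenchyme), open points did not, and bars are list medians, which run from −4.36 for fibroblast genes to 4.49 for epithelial junction genes.

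All 16 endothelial markers were higher in mesenchyme, over all genes and adjusted over the list alone (median −3.54, adjusted p = 3.58e-15). Among them were Sox17 (−5.21 ± 0.42), the VE-cadherin gene Cdh5 (−4.94 ± 0.42) and the receptor gene Tek (−4.32 ± 0.51), and the median marker kept 6.72% of its mesenchymal signal in epithelium. With only genes above the median signal, which tests fewer genes, the count was 9. Of 17 macrophage and leukocyte markers 9 were higher in mesenchyme, and 14 adjusted over the list alone (median −1.56, adjusted p = 2.07e-07), with Csf1r at −3.97 ± 0.34, Mrc1 at −2.93 ± 0.33 and Pf4 at −2.84 ± 0.46. The count was 15 with array weights and 4 with only genes above the median signal, and in mesenchyme 1 the list's log2 signals lay on average at −0.32 from the mean of the mesenchyme arrays. Of 12 red cell markers 4 were higher in mesenchyme by both counts (median −0.82, adjusted p = 0.0304), with adjusted p = 0.334 with an estimated correlation. Hbb-bh1 (−1.87 ± 0.45), Alas2 (−1.66 ± 0.40) and Hba-x (−1.47 ± 0.41) were among them. Alas2 lost its call without mesenchyme 2 (−1.38) or epithelium 7 (−1.67), Hba-x after quantile normalization (−1.28) and Hbb-bh1 in the mean of its probe sets (−1.44). Hbb-bh1 and Hba-x lost theirs without mesenchyme 1 (−1.55 and −1.14), mesenchyme 4 (−1.80 and −1.498), epithelium 5 (−1.79 and −1.47) or epithelium 7 (−1.65 and −1.27). The red cell count was 2 without mesenchyme 1, mesenchyme 2 or epithelium 5 and in the mean of probe sets, 1 without mesenchyme 4 and 0 without epithelium 7, and the list was not past the test without mesenchyme 1 or epithelium 8 or with array weights. Without both mesenchyme 1 and epithelium 5 the counts were 16 endothelial, 9 macrophage and 2 red cell markers. In that fit Hbb-bh1 (−1.47) and Hba-x (−1.14) were not past the test.

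Of 18 neural and neural crest markers 5 were higher in mesenchyme and 2 in epithelium (median −0.29, adjusted p = 0.637), and 6 and 2 adjusted over the list alone. The neurofilament gene Nefm was higher in mesenchyme (−3.38 ± 0.47), whereas the receptor genes Erbb3 (5.10 ± 0.28) and Ret (3.498 ± 0.46) were higher in epithelium. Both receptors are known outside nerves too, and Ret also stands in the list of Wolffian and ureteric duct markers. In mesenchyme 1 the list's log2 signals lay on average 0.46 above the mean of the mesenchyme arrays. The neural count in mesenchyme was 3 without mesenchyme 4, after quantile normalization or with only genes above the median signal, and 2 without epithelium 5, epithelium 7 or epithelium 8, or without both mesenchyme 1 and epithelium 5. Of 13 mesothelial markers 7 were higher in mesenchyme and 3 in epithelium (adjusted p = 0.828), and 7 and 4 adjusted over the list alone; the median was −1.26, while the mean was 0.08. Those higher in epithelium were Msln (5.16 ± 0.48), Upk1b and Krt19 (4.49 ± 0.31), of which the latter pair also stand in the epithelial lists. The count in mesenchyme was 4 without mesenchyme 4 and 3 without epithelium 7 or with only genes above the median signal, and with array weights 5 were higher in epithelium.

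Of 12 Wolffian and ureteric duct markers 4 were higher in epithelium and 0 in mesenchyme, and 4 and 2 adjusted over the list alone. They included Ret, Gata3 (3.31 ± 0.33) and Gfra1 (2.64 ± 0.27). The list's median was −0.05, while its mean of 0.56 and its test pointed to epithelium (adjusted p = 0.108). The count in mesenchyme was 2 without mesenchyme 2 and 1 with array weights, and the list was past the test without epithelium 5, without both mesenchyme 1 and epithelium 5 and with only genes above the median signal. Of 14 hindgut and intestinal markers 3 were higher in epithelium, by both counts (median 0.14, adjusted p = 0.140): Fabp1 (2.27 ± 0.39), Cdh17 (2.25 ± 0.48) and Vil1 (1.41 ± 0.40). Cdh17 and Vil1 lost their calls without epithelium 7 (2.10 and 1.16), which left a count of 1. Vil1 lost its call also without mesenchyme 1 (1.33), mesenchyme 2 (1.45), mesenchyme 4 (1.46) or epithelium 8 (1.35) and with a pseudocount of 1 (2.06). The list was past the test without mesenchyme 1, with array weights and in the mean of probe sets.

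Immediate early and heat shock genes, which can respond to dissection, differed in both directions. Of 25, 4 were higher in mesenchyme and 3 in epithelium, and 5 and 3 adjusted over the list alone (adjusted p = 0.828). The median was −0.18 and the mean −0.12, while the test pointed to epithelium, and the mean changed sign with arrays centred on their medians or without epithelium 5. Klf2 (−2.66 ± 0.42) and Ccn1 (−1.99 ± 0.31) were higher in mesenchyme, and the heat shock gene Hspa1b (2.78 ± 0.36) was higher in epithelium, while its near-identical copy Hspa1a differed by −0.22 and was not past the test. In the mean of its probe sets Ccn1 was not past the test (−0.71). The count in epithelium was 1 without mesenchyme 2, mesenchyme 4 or epithelium 7, and the count in mesenchyme was 2 without mesenchyme 1, mesenchyme 2, epithelium 5 or epithelium 8 and with median centring. With array weights or the actin ratio as a covariate 5 were higher in epithelium. Without both mesenchyme 1 and epithelium 5 the counts were 5 in epithelium and 2 in mesenchyme.

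Sex-linked genes were read on each array, since the labels give the sex as unknown. Xist, transcribed from the inactive X chromosome, had a signal of 6752 on mesenchyme 1, 8507 on mesenchyme 2, 534 on mesenchyme 4, 925 on epithelium 5, 1837 on epithelium 7 and 39165 on epithelium 8. The Y-linked gene Eif2s3y had 126, 1318, 3668, 7590, 4179 and 42.7 on the same arrays in that order. Kdm5d, also on the Y chromosome, had 3.35, 201, 665, 766, 645 and 25.5, and Uty 177, 284, 368, 1408, 475 and 15.0. Neither compartment held arrays of a single pattern, and none of these genes differed between compartments past the test.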

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

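The fit with the actin ratio and the fit of 4 arrays were added after the data were seen. Scaling moved the median log2 difference of all genes from −0.11 to −0.02 with quantile normalization and 0.08 with median centring, and the share of calls higher in epithelium from 39.4% to 43.4% and 46.3%. Of 36 alternative counts of genes, 32 lay within 1.5 times the main count, as did 613 of 702 counts of list members; 347 of 373 list results and 1233 of 1299 results for named genes kept their direction and side of the threshold. Array weights gave 2055 genes higher in epithelium and 2996 higher in mesenchyme. With only genes above the median signal, which tests fewer genes, 998 were higher in mesenchyme. Leaving out each array gave 660 (without epithelium 7) to 1059 genes higher in epithelium and 1138 to 1678 higher in mesenchyme.

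Of list means, median centring turned FGF genes to 0.0027, cell cycle genes to 0.034 and immediate early genes to 0.068. The filter on dim genes turned neural markers to 0.42, took Wnt genes below the threshold (−0.87) and Wolffian markers past it (2.08). Array weights took red cell markers below it (−0.66) and hindgut markers past it (0.61), as did the mean of probe sets (0.45). An estimated correlation, which leaves the means as they were, took smooth muscle (−2.91), Hox (0.44), Wnt (−0.75), BMP and TGF-beta (−1.05) and red cell genes (−0.85) below it. The 4 arrays took Wnt genes (−0.60) and red cell markers (−0.69) below it and Wolffian markers past it (0.94). Leaving out each array gave −1.02 to −0.63 for red cell, −0.021 to 0.27 for mesothelial, 0.25 to 0.58 for hindgut, 0.32 to 0.56 for Hox, 0.37 to 0.76 for Wolffian and −0.20 to 0.038 for immediate early genes.

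Among named genes, 3 that were not past the test changed sign. Rrm2 was −0.058 with quantile normalization, −0.41 as the mean of its probe sets and −0.14 to 0.30 with an array left out. Top2a was −0.15 with quantile normalization, −0.0092 with the actin ratio, −0.051 with 4 arrays and −0.11 to 0.16 with an array left out. Upk3b was −0.24 with array weights, −0.18 with 4 arrays and −0.58 to 0.68 with an array left out. The cause was not tested in these cases. Dim probe sets limit what can be seen, since signals near the added 45 carry little difference.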

Other observations

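The gene families, and all tests here except that on splits of the arrays, were chosen after the data were seen. 12 families were counted by symbol. The collagen chain genes, the fibrils and sheets of the matrix, were higher in mesenchyme for 23 of 42 measured members and in epithelium for 2, of which 17 members also stand in the fixed lists. Outside those lists Col14a1 differed by −5.32 ± 0.34 and Col12a1 by −4.52. The epithelial members were Col4a5 (1.97) and Col4a6 (1.77), chains of the basement membrane's type IV collagen. Of the other type IV chains, Col4a1 (−3.44) and Col4a2 (−3.70) were higher in mesenchyme, and Col4a3 and Col4a4 were not past the test. Of 31 ADAMTS and matrix metalloprotease genes 11 were higher in mesenchyme, among them Mmp2 (−4.41) and Adamts9 (−3.27), and 2 in epithelium, Adamts18 (3.09) and Mmp11 (0.98). That epithelial count was 1 with median centring and without mesenchyme 1, mesenchyme 2, mesenchyme 4, epithelium 7 or epithelium 8. Of 13 imprinted genes, many of which regulate fetal growth, 8 were higher in mesenchyme and 0 in epithelium, with Dlk1 at −4.78, Mest at −4.56 and Igf2 at −1.65; with median centring the count was 6.

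Of 31 semaphorin, plexin and neuropilin genes 10 were higher in mesenchyme, among them the receptor genes Nrp2 (−4.91) and Nrp1 (−3.88) and the ligand genes Sema6d (−3.24), Sema3g (−3.18), Sema5a (−2.62) and Sema3a (−2.44), and 5 in epithelium, among them the ligand genes Sema3c (2.49) and Sema3e (1.97) and the receptor gene Plxnb1 (1.06). Without mesenchyme 2, epithelium 7 or epithelium 8 the epithelial count was 3. Of 18 Notch pathway genes 5 were higher in mesenchyme, including Jag1 (−3.78) and Hey1 (−2.92), and 2 in epithelium, Jag2 (1.27) and Notch1 (1.10); the epithelial count was 0 without mesenchyme 4, epithelium 5 or epithelium 7 and 1 without mesenchyme 1, mesenchyme 2 or epithelium 8. Of 16 serine protease genes (Hpn, St14, Prss8, Prss22 and the measured Tmprss genes) 7 were higher in epithelium and 0 in mesenchyme, with Tmprss2 at 6.75 and St14 at 5.59. Of 11 S100A genes 4 were higher in epithelium and 0 in mesenchyme, led by S100a14 (3.90). The counts in epithelium and mesenchyme were 3 and 5 of 21 Eph receptor and ephrin genes, 2 and 5 of 20 integrin genes, 0 and 5 of 12 T-box genes, 7 and 2 of 44 keratin genes and 1 and 1 of 11 aquaporin genes. The Eph count in epithelium was 1 without mesenchyme 1, epithelium 7 or epithelium 8, and that in mesenchyme 3 without mesenchyme 4 or epithelium 8. The integrin count in epithelium was 1 without mesenchyme 4, epithelium 7 or epithelium 8. The T-box count in epithelium was 1 without mesenchyme 1 or without both mesenchyme 1 and epithelium 5. The keratin count in mesenchyme was 0 without epithelium 7, and 1 without mesenchyme 2, mesenchyme 4, epithelium 5 or epithelium 8 and with median centring. The aquaporin count in epithelium was 2 with quantile normalization or median centring. No called member of these families changed direction under quantile normalization or median centring.

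All 10 splits of the 6 arrays into 3 and 3 were fitted, and 1 of them, the true one, called 2676 genes, while the highest count of the others by limma was 0. At an unadjusted p under 0.05 the true split gave 4544 genes and the others 226 to 1629. With 10 splits no share under 0.05 can be reached. Each of the other splits also mixes both compartments within its groups, so the compartment difference adds to their spread and lowers their calls. Their counts therefore do not show what a grouping without a real difference would give.

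Mesenchyme 1 differed from the other mesenchyme arrays: its log2 signals deviated from the group mean with an SD of 0.58, against 0.39 and 0.38 for mesenchyme 2 and 4. A candidate explanation is RNA integrity or amplification, since its actin ratio is near that of epithelium 5. Its median hybridisation control signal is near too (16043, and 16510 on epithelium 5). Its Gapdh ratio of 11.5 is not (26.3 on epithelium 5) and is the lowest of the mesenchyme arrays. Across genes, the slope on the actin ratio within mesenchyme correlated with the slope within epithelium at r = 0.254. That r was the highest of 36 orders of the arrays but close to the next, 0.2497. It was too low to decide by a bound that was set after r was seen. More cells of another type may also contribute. Among 10000 random lists of like signal, 2 of 9 lists of other cell types ranked in the top 2.5%, the epithelial (percentile 99.4) and the neural (99.3), while smooth muscle (0) and macrophage genes (0.28) ranked in the lowest 2.5%, so these explanations cannot be told apart with 3 arrays.

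Mesenchyme 2 had signal both at Xist, 8507 against 534 on mesenchyme 4, and at Y-linked genes. RNA of both sexes in the sample may explain this, although the labels say that samples were not pooled. Of 3 measured Y-linked genes 2 (Eif2s3y and Kdm5d) were more than 2-fold above both arrays with the lowest Y-linked signal, a level that 5.31% of all probe sets reached, and Uty was not. With 3 genes and no array known to be of mixed sex the question stays open, and no biological explanation was tested.

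Upk3b had like signals in both compartments (log2 difference 0.18), unlike Upk1b and Upk3a. Carry-over of urothelium into the mesenchyme arrays is argued against, since genes of epithelial junctions and keratins kept at most 23.6% of their epithelial signal there (F11r), with a median of 4.25%, where Upk3b kept 104%. Upk3b is also expressed by mesothelium, the lining of the body cavity. Mesothelial cells in the mesenchyme fraction may be its source, as a hypothesis. Of 10 measured mesothelial genes outside the epithelial lists 7 were higher in mesenchyme, including Aldh1a2 (11336 ± 1501 there), Wt1 and Lrrn4. Only 1, Msln, was higher in epithelium, with 2532 ± 1244 there and 23.8 ± 23.0 in mesenchyme. The low Msln signal in mesenchyme does not go with this hypothesis, though 1 dim gene cannot decide it. The count of 7 was 4 without mesenchyme 4 and 3 without epithelium 7, the whole mesothelial list was not past the test (adjusted p = 0.828), and several of these genes are also expressed by mesenchyme, so the mesothelium is not singled out.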
